A study of Drosophila melanogaster with 6 samples.

How the data were processed

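Total RNA was extracted from whole embryos of 2 Drosophila melanogaster genotypes, OreR and the caper mutant CC01391, with TRIzol and DNase I treatment. Libraries were made with a stranded Illumina kit and sequenced as read pairs on a HiSeq instrument, per the labels' protocols. The sample titles gave each library its genotype and a biological replicate number from 1 to 3, and these titles were the only basis of grouping. Eggs were collected on apple juice plates, and the collection window was not given in the sources used here.

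The authors deposited a single table made for JunctionSeq, per the file headers, with 73704 exonic bins, 54271 annotated splice junctions and 418 unannotated splice junctions of 14737 genes. GSNAP 2014-12-17 and SAMtools are listed as tools, and BDGP5 and mm10 as genome builds, per the submitters' processing notes; the role of each, the gene annotation, the counting tool, its version and its treatment of strand are not given in the sources used here. Raw values were deposited as counts of each feature and, in separate columns, as the counts of the rest of the gene. The deposited table also held each count divided by a size factor of its library, which is a normalised signal; the factors recovered from the values were 1.005, 1.123 and 0.965 for OreR replicates 1 to 3 and 1.097, 0.875 and 0.979 for mutant replicates 1 to 3, and this signal was used only for that check. The feature count plus the count of the rest gave the same gene count for every feature of a gene, except in 48 genes where a feature exceeded its gene and the rest was listed at 0; the smallest sum was used. Gene counts summed to 36299246, 40241577 and 34815930 for OreR replicates 1 to 3 and to 42905168, 36979138 and 42956396 for mutant replicates 1 to 3. A read pair can enter several bins and junctions, so feature counts do not add up to gene counts. Counts of 0 in all 6 libraries were found in 1458 genes and 9221 features.

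Gene identifiers were matched to symbols in a reference table of the BDGP6 assembly, which named 14100 genes and left 637 unnamed. Because the build of the deposited table differs, that assembly served only for names and for the order of neighbouring genes, no coordinates are printed, and features keep the identifiers of the deposited table. Overlapping genes were often not separate entries of the table, and caper was not analysed here, so its level and the levels of its bins and junctions are not reported.

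Gene counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest with genotype as the only term). P-values were adjusted by the Benjamini-Hochberg method at 0.05 over the 10251 genes that passed the filter. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. CPM are counts scaled to the TMM-adjusted library size, and log2 CPM used a prior count of 2. Usage was tested with diffSpliceDGE of edgeR on bins and junctions together, which compares each feature with its gene and gives a Simes p per gene, since JunctionSeq itself was not run here. Shares are feature counts as a percent of gene counts. Kinds of feature and overlaps of gene sets were compared with Fisher's exact test. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The lists covered developmental stage (maternal, early zygotic patterning, cuticle and chitin), embryonic tissues (neuroblast and proneural, neuron and synapse, sensory neuron and dendrite, glia, muscle, trachea, hemocyte, fat body and yolk, gut, germline), tissues an egg collection should lack (chorion, testis), splicing (splicing factors, classic alternative splicing targets, sex determination and dosage), stress and strain (heat shock, immune, detoxification, strain background) and general programmes (Hox, ecdysone, cell cycle and replication, Notch, EGFR and Wnt signalling, oxidative phosphorylation, cytosolic and mitochondrial ribosomal proteins, histones). Some genes are in several lists: 25 of the 30 classic splicing targets, 14 of the 36 maternal genes and 12 of the 19 sex determination genes are also members of another.

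The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where stated. The rule took caper, the 12 largest increases and 12 largest decreases among changed genes with a mean log2 CPM of at least 1 and no overlap between genotypes, the 4 members with the smallest p in each list that passed camera or held at least 3 changed members, the 15 genes with the smallest Simes p with the feature of smallest p in each, and the splicing targets and sex determination genes with changed usage. Folds against a group with 0 counts are lower bounds from a floor of 3 counts over the group, and ratios against 1 to 3 counts carry an exact 95% binomial interval; floors and intervals cover counting error only. No pair of replicates was found to be a duplicate: the chi-square per degree of freedom between libraries of the same genotype was 28.4 to 83.4.

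The tests were checked on simulated counts with the means, dispersions and depths of these libraries, in which 200 genes or features were changed. The data held far more changes, with 46.9% of tested genes and 1618 of 88820 tested features called. Recovery depends on that share, so the simulated values need not hold for these data. With so few changed genes the simulation also did not test the choice of scaling. For the gene test over 10251 genes, 44% of genes raised 1.5-fold, 74% of those raised 2-fold, all 50 raised 4-fold and 88% of those halved to 0.5 were recovered, with 5.56% of calls false. For the usage test over 90337 features, recovery was 18%, 68%, 96% and 70% in that order (9, 34, 48 and 35 of 50 features). Of its 193 calls, 5.18% fell in genes without a changed feature. Calls on unchanged features of genes that held a changed feature were not counted, so 5.18% is a lower bound on false feature calls. In the list test a list of 40 genes raised 1.4-fold was found and 0 of 29 lists without change were called by camera; these simulated genes were independent of each other.

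Alternatives were DESeq2 1.42.0, DESeq2 size factors and upper quartile scaling in edgeR, no filter on low counts, gene counts rebuilt from exonic bins or from annotated junctions, a 2-fold minimum, limma voom with diffSplice, bins or junctions alone, feature filters of 10 summed counts or a mean of 50, the gene F test, the replicate number as a block, and leaving out each library. A run without mitochondrially encoded genes was added after seeing the data.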

Results

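RNA was measured in whole-embryo lysates of Drosophila melanogaster from the wild-type strain OreR (Oregon-R) and from a strain carrying the CC01391 allele of caper, a gene for an RNA-binding protein of the splicing machinery related to vertebrate RBM39. There were 3 biological replicates of each genotype, sequenced together in a single lane, and the age of the embryos was not given in the sources used here. The deposited table held counts for exonic bins, annotated splice junctions and unannotated splice junctions, from which a count per gene was recovered. OreR libraries held 36299246, 40241577 and 34815930 gene counts and mutant libraries held 42905168, 36979138 and 42956396, spread over 14737 genes and 128393 features. The series set out to compare gene levels and isoform choice between the genotypes. Counts of caper itself were not analysed here, so the genotype labels were not checked through the mutated gene.

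Embryos of the caper mutant differed from OreR embryos in the level of a large part of the transcriptome. All mutant libraries came from the CC01391 strain and all others from OreR. Effects of the caper allele and of strain background therefore cannot be told apart in any comparison below. Of 10251 genes tested, 4811 (46.9%) changed, 2702 of them higher and 2109 lower in the mutant (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The median absolute log2 fold change of changed genes was 0.725, and 1309 genes changed at least 2-fold, 663 upward and 646 downward. 48 of 70 splicing factors and 20 of 40 cell cycle genes rose, and 23 of 42 neuron and synapse genes and 16 of 31 muscle genes fell (40, 17, 34 and 21 in that order with upper quartile scaling). At the extremes, 54 genes were at least 8-fold higher and 64 at least 8-fold lower. The 3 OreR values and the 3 mutant values did not overlap for 60.4% of tested genes, against 10% by chance. Correlations of log2 CPM (counts scaled to library size) across genes lay between 0.989 and 0.996 for libraries of the same genotype and between 0.938 and 0.968 for libraries of different genotypes, and the first principal component held 78.9% of the variance. The balance of directions depended on scaling and on the libraries used: with upper quartile scaling 2269 genes were higher and 3566 lower (38.9% higher, against 56.2% with TMM), because that scaling moved the median log2 fold change of all tested genes from -0.07 to -0.23, a shift of -0.16. Leaving out mutant replicate 2 lowered the count of changed genes to 3169, with 2194 higher and 975 lower (69.2% higher), and leaving out mutant replicate 3 lowered it to 3633, with 2351 higher and 1282 lower.

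Several of the 12 largest increases took genes from near absence in OreR to clear expression in the mutant. Others started higher, such as GstE1 and FBgn0010549 at means of 4.33 and 1.86 CPM in OreR. mthl8 (FBgn0052475), a member of the methuselah-like family of receptors, had 2 counts over the 3 OreR libraries and 2460 over the 3 mutant libraries, a ratio of 1270 with a 95% counting interval from 351 to 10500. S-Lap1 (FBgn0035915), a leucyl aminopeptidase of the sperm proteome, rose from 0.14 ± 0.08 to 79.3 ± 7.73 CPM (SD, n = 3), and CG2961 rose from 0.25 ± 0.14 to 122.3 ± 69.3 CPM. The glutathione S-transferase genes GstO1 (FBgn0035907) and GstE1 (FBgn0034335) rose 70.0-fold and 17.6-fold, with log2 fold changes of 6.13 ± 0.22 (SE) and 4.13 ± 0.18. The gene FBgn0010549 rose 20.4-fold, CG11893, CG32572, CG31683, CG42831 and CG34437 rose between 16.8-fold and 116.6-fold, and CG13361 rose from 97 counts over the 3 OreR libraries to 1513 over the 3 mutant libraries. The 116.6-fold rise was that of CG11893, whose log2 fold change of 6.87 ran from 6.455 to 8.157 on leaving out each library. Adjusted p-values of these 12 genes in the edgeR test ran from 8.3e-06 to 0.00029.

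The largest decreases were of the same order. CG3588 (FBgn0025643) fell from 63.4 ± 9.59 CPM to 3 counts over the 3 mutant libraries, a ratio of 2450 (95% counting interval 840 to 11900), CG14419 from 1570 counts to 2 (ratio 760, interval 210 to 6280) and CG9582 from 723 counts to 1 (ratio 700, interval 125 to 27700). LManV and LManVI, which encode lysosomal alpha-mannosidases and lie side by side, fell 29.5-fold and 31.8-fold. Ada1-1 fell 124.7-fold, CG14691 39.4-fold and CG32640 33.2-fold. The remaining 4 of the 12 largest decreases were transcripts of the mitochondrial genome. mt:CoI (FBgn0013674), which encodes subunit I of cytochrome c oxidase, fell from 3040.1 ± 325.7 to 11.3 ± 5.11 CPM, and mt:CoII from 1705.9 ± 192.4 to 9.29 ± 2.86 CPM. mt:ND1 and mt:Cyt-b fell 202.6-fold and 192.5-fold. Of the other 2 tested, mt:ND5, chosen after its values were seen, had 14.8 ± 5.25 CPM in OreR and 11.3 ± 1.27 CPM in the mutant (adjusted p = 0.22 in the edgeR test). mt:ND6, also chosen after its values were seen, had 76 counts over the 3 OreR libraries and 0 over the 3 mutant libraries (adjusted p = 0.0011). Adjusted p-values of the 12 largest decreases ran from 1.1e-05 to 0.00049. Counts of LManV, LManVI, CG32640 and GstE1 are uncertain where reads are shared with near-identical neighbouring copies.

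**Figure D1:**
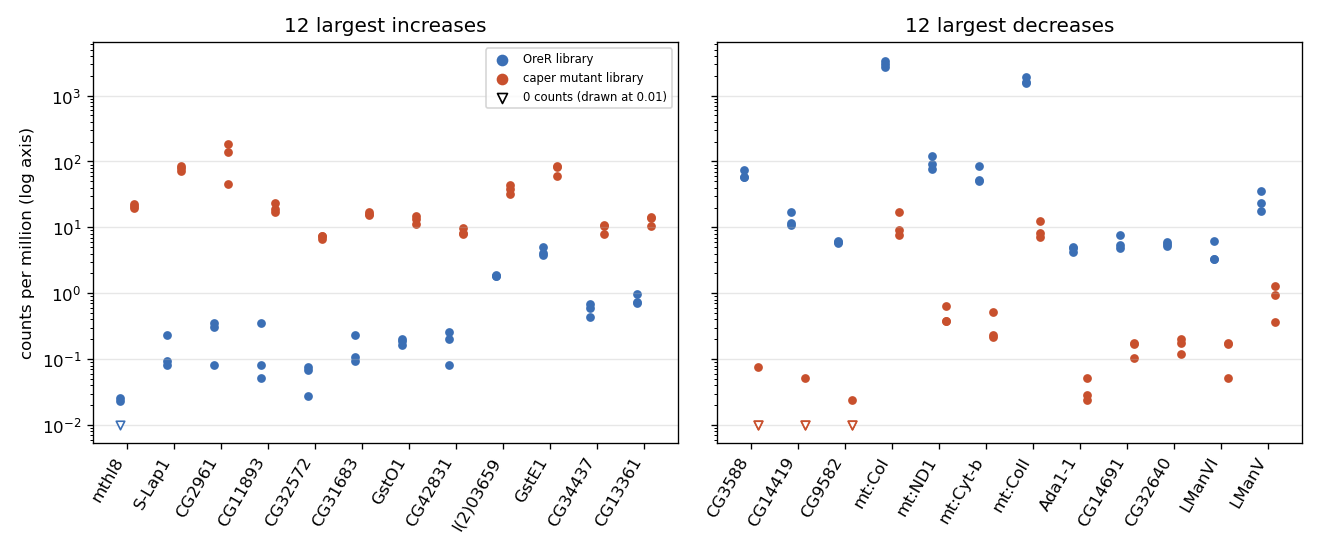
CPM (log axis) of the 12 genes with the largest increases (left) and the 12 with the largest decreases (right), each point being a library, blue for OreR and red for the caper mutant; open triangles mark libraries with 0 counts, drawn at 0.01. Only genes in which the 3 libraries of each genotype lie apart from those of the other were eligible. The gene mt:CoI is at 3040.1 CPM on average in OreR and 11.3 CPM in the mutant.

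The lists of splicing factors, of sex determination and dosage compensation, and of cell cycle and replication held more increases than decreases and passed a competitive set test (camera with a preset correlation of 0.01, adjusted p = 3.5e-06, 0.017 and 0.0014 in that order). Each call was lost with an estimated correlation (adjusted p = 0.835 for each of the 3). With directional fry the splicing factor and sex determination lists passed (adjusted p = 0.018 and 0.012) and the cell cycle list did not (0.089). Of 70 tested splicing factors, 48 rose and 6 fell (56 changed when adjusted over the list alone), with a median log2 fold change of 0.49. With upper quartile scaling 40 rose and 10 fell. U2af38, the small subunit of the U2 auxiliary factor that recognises the 3' splice site, rose 2.09-fold (log2 fold change 1.06 ± 0.11), the RNA helicase gene pea rose 2.29-fold, hfp rose 1.62-fold and Srp54 rose 1.60-fold. The 6 that fell were ps, btz, fne, bru3, bru2 and sm, with log2 fold changes from -0.62 to -0.36; fne and the bru genes encode RNA-binding proteins of the ELAV and CELF families. In the list of sex determination and dosage compensation, 10 of 19 genes rose and 1 fell (11 when adjusted over the list alone; median 0.51), or 9 and 2 with upper quartile scaling. The increases included mof, the acetyltransferase of the dosage compensation complex (2.15-fold), gro (1.94-fold), ix (1.68-fold) and fl(2)d (1.54-fold), whereas the noncoding RNA lncRNA:roX1 fell from 589.0 ± 20.8 to 490.1 ± 24.2 CPM. Of 40 cell cycle and replication genes, 20 rose (20 when adjusted over the list alone; median 0.31), and with upper quartile scaling 17 rose and 2 fell. The spindle checkpoint genes BubR1 and mad2 rose 2.32-fold and 2.39-fold, the replication licensing gene dup 2.04-fold and the cytokinesis gene tum 2.30-fold.

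The maternal, germline, cytosolic ribosomal and signalling lists held more increases than decreases with TMM scaling and did not pass camera. Among 36 maternal genes, 13 rose and 4 fell (17 when adjusted over the list alone; camera adjusted p = 0.18). Increases included bcd, the anterior determinant (2.97-fold), the mRNA regulator smg (2.86-fold), fs(1)K10 (1.78-fold) and pum (1.78-fold), and the median of the list, 0.07, turned to -0.08 with upper quartile scaling, under which 12 rose and 7 fell. In the germline list, 6 of 24 rose and 1 fell (6 when adjusted over the list alone; adjusted p = 0.18), or 5 and 5 with upper quartile scaling, the increases including the piRNA pathway genes mael (3.01-fold), tej (3.02-fold), AGO3 (2.95-fold) and zuc (2.27-fold). Of 74 cytosolic ribosomal protein genes, 31 rose and 1 fell (32 when adjusted over the list alone, camera adjusted p = 0.095). With upper quartile scaling 8 rose and 7 fell. Unlike the maternal, germline and signalling lists, the cytosolic ribosomal list passed directional fry (adjusted p = 0.021). The increases were small, such as RpL5 (1.39-fold) and RpL24-like (1.45-fold), the largest being RpS14b (1.66-fold), whereas RpS10a, a second copy of the RpS10 gene, fell 20.8-fold. In the list of Notch, EGFR and Wnt signalling, 13 of 40 rose and 5 fell (21 when adjusted over the list alone; adjusted p = 0.39), the increases including dsh (1.83-fold), Mad (1.97-fold), H (1.98-fold) and Ras85D (1.60-fold). With upper quartile scaling 10 rose and 15 fell, and the median of 0.02 turned to -0.14.

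Among lists of differentiated tissues, those of neurons, cuticle, muscle, gut and hemocytes held more decreases than increases and passed camera with the preset correlation (adjusted p = 0.00011, 0.00076, 0.0056, 0.0043 and 0.013 in that order). Their calls were lost with an estimated correlation (adjusted p = 0.60 for gut and 0.835 for each of the other 4). That correlation was 0.23 to 0.43 in the other 4 lists. For gut it was 6.3e-05, below the preset 0.01, so a higher correlation between its genes does not explain the loss of its call. A call lost with the estimated setting of camera therefore does not by itself show correlated genes. With directional fry the gut list passed (adjusted p = 0.0051). The neuron, cuticle, muscle and hemocyte lists did not pass directional fry (0.073, 0.14, 0.081 and 0.052 in that order). Of 42 neuron and synapse genes, 23 fell and 2 rose (29 changed when adjusted over the list alone), with a median log2 fold change of -0.62. Appl, the neuronal relative of the amyloid precursor protein, fell from 179.9 CPM in OreR with a log2 fold change of -1.71 ± 0.12, and the netrin receptor gene fra changed by -0.80 ± 0.12. The 2 that rose, the synaptic vesicle genes Csp and unc-13, were 1.52-fold and 1.57-fold higher. Of 71 cuticle and chitin genes, 18 fell and 2 rose (19 changed when adjusted over the list alone; median -0.96). The genotypes overlapped in the mean log2 CPM of this list, taken relative to the OreR mean. It was 0.55, -0.06 and -0.49 in OreR replicates 1 to 3 and -0.486, -0.61 and -1.28 in mutant replicates 1 to 3. The cuticle protein gene Lcp3 fell from 53 counts to 1 (ratio 51.3, 95% counting interval 8.83 to 2070), Cpr47Ef, also a cuticle protein gene, fell 6.74-fold, and the chitinase gene Cht10 fell 1.53-fold, whereas Cpr72Ec rose 4.20-fold at a low level. Of 31 muscle genes, 16 fell and 1 rose (20 when adjusted over the list alone; median -0.58), among them Mhc, the muscle myosin heavy chain (2.09-fold lower), TpnC47D, a troponin C (2.47-fold lower), and sns, a receptor of myoblast fusion (1.68-fold lower). The gene cpb, a subunit of actin capping protein, was 1.37-fold higher. Of 24 gut genes, 11 fell (11 when adjusted over the list alone; median -0.56). The maltase genes Mal-A1 and Mal-A4 fell 3.61-fold and 3.64-fold, the protease gene Jon65Aiv fell 3.51-fold and Vha55, a proton pump subunit, fell 1.56-fold. Of 21 hemocyte genes, 12 fell and 1 rose (13 when adjusted over the list alone; median -0.50), led by the matrix genes Tig (1.81-fold lower), LanA (1.47-fold), LanB1 (1.44-fold) and the type IV collagen gene vkg (2.24-fold). With upper quartile scaling 34, 29, 21, 17 and 13 genes of these 5 lists fell, in the order given.

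The glial and immune lists also passed camera as lower (adjusted p = 0.033 for both), though not with every library left out. Neither passed with the replicate number as a block. Both calls were lost with an estimated correlation (0.835). With directional fry the immune list passed (adjusted p = 0.026) and the glial list did not (0.052). Of 16 glial genes, 9 fell (9 when adjusted over the list alone, 12 with upper quartile scaling; median -0.35), including the septate junction genes Gli and Nrx-IV, ths and the receptor gene moody (log2 fold changes -0.49, -0.46, -0.46 and -0.36). Of 22 immune genes, 9 fell and 4 rose (13 when adjusted over the list alone; median -0.34), or 13 and 4 with upper quartile scaling. Drsl5 fell 8.89-fold, Dso1 7.04-fold and the lysozyme gene LysD 7.77-fold, whereas the Toll-responsive peptide gene BomS1 rose 26.8-fold. LysD and BomS1 have near-identical copies and their counts are uncertain. The log2 fold change of BomS1, 4.75 with all libraries, ran from 4.35 to 5.84 on leaving out each library. Both calls ended when OreR replicate 2 was left out (0.059) or mutant replicate 1 was left out (0.068); the glial call also ended without mutant replicate 2 (0.078) and the immune call without mutant replicate 3 (0.080). In the list of eye colour, body colour and strain background genes, 7 of 14 fell (7 when adjusted over the list alone, median -0.49). Its camera adjusted p was 0.015, and 0.835 with an estimated correlation, and it passed directional fry (adjusted p = 0.026). The eye pigment transporter gene w had 24.7 ± 5.83 CPM in OreR and 5.97 ± 0.29 CPM in the mutant, Cyp12a4 fell 7.61-fold, ry 1.67-fold and bw 1.60-fold.

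**Figure D2:**
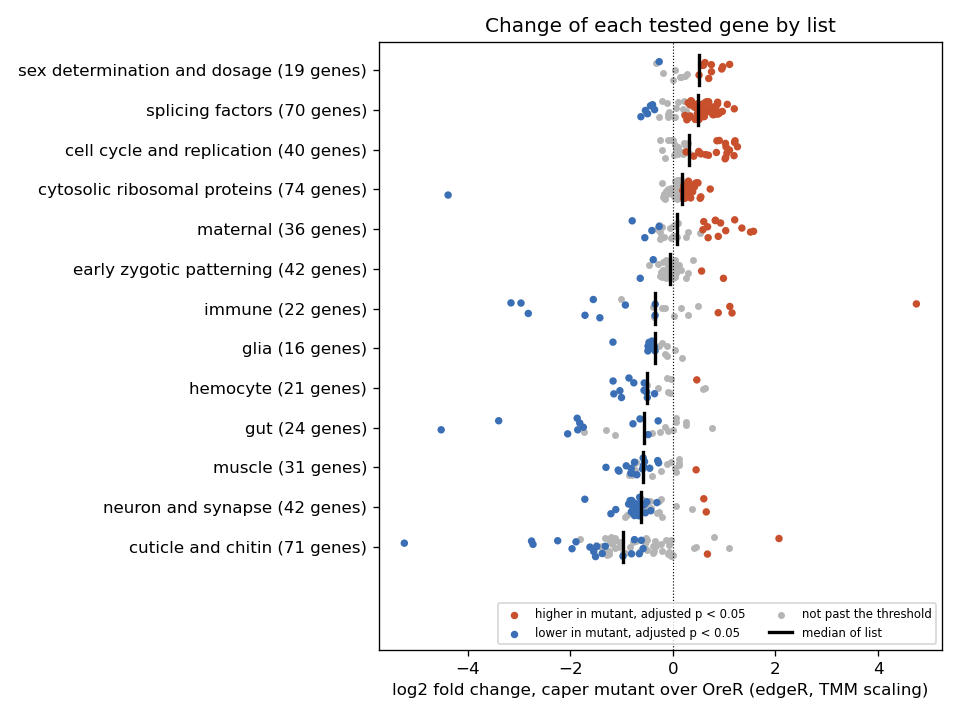
Log2 fold change of each tested gene (mutant over OreR, TMM scaling) in 13 lists fixed before the data were examined, ordered by median (black bar); red and blue points are genes past an adjusted p of 0.05 and grey points are not. Medians run from -0.96 in cuticle and chitin genes to 0.51 in sex determination and dosage genes, and with upper quartile scaling all lie lower, the maternal median turning from 0.07 to -0.08.

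Genes of detoxification changed in both directions. Of 72 tested, 19 rose and 28 fell (52 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.77). Cyp4e2, a cytochrome P450 gene, rose 7.01-fold (log2 fold change 2.81 ± 0.09), GstD5 rose 7.83-fold and GstE7 9.40-fold, the GstD and GstE genes being clustered copies whose counts are uncertain. Of 19 heat shock and chaperone genes, 2 rose and 5 fell (6 when adjusted over the list alone; adjusted p = 0.27), or 1 and 8 with upper quartile scaling, the abundant mitochondrial chaperone gene Hsc70-5 falling 1.45-fold, Hsp60A 1.33-fold and Hsc70-3 1.25-fold. Hsp70Ba rose 7.82-fold, and its counts are uncertain because the Hsp70 genes are near-identical. Its log2 fold change of 2.97 ran from 2.30 to 3.63 on leaving out each library. The call of Hsc70-3 ended without OreR replicate 3 (adjusted p = 0.076) or without mutant replicate 2 (0.072), and the direction of Hsp60A turned when annotated junctions alone were counted (log2 fold change 0.13, adjusted p = 0.34). Of 38 nuclear genes of oxidative phosphorylation, 14 fell and 4 rose (18 when adjusted over the list alone; adjusted p = 0.11), or 21 and 2 with upper quartile scaling, with small changes such as ND-75 and ATPsynbeta (1.30-fold and 1.26-fold lower) and ND-42 and ATPsynG (1.32-fold and 1.33-fold higher). Of 69 mitochondrial ribosomal protein genes, 13 rose and 10 fell (18 when adjusted over the list alone; adjusted p = 0.58). The genes mRpL1, mRpS7, mRpS10 and mRpL50 rose by 0.43 to 0.58 on the log2 scale, and with upper quartile scaling 4 rose and 24 fell.

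The next 7 lists did not pass camera with all libraries, and each held more decreases with upper quartile scaling than with TMM. Of 42 early zygotic patterning genes, 2 rose and 2 fell (3 when adjusted over the list alone; camera adjusted p = 0.43). slam, needed for cellularisation, rose 1.98-fold and sisA 1.48-fold, and tld and en fell 1.55-fold and 1.30-fold. The call of sisA ended with upper quartile scaling (adjusted p = 0.061), under which 1 gene of the list rose and 10 fell. Of 13 Hox genes, Scr, Dfd, Antp and abd-A fell by 0.36, 0.40, 0.27 and 0.34 on the log2 scale (0 changed by edgeR when adjusted over the list alone; camera adjusted p = 0.14), with upper quartile scaling 9 fell, and without mutant replicate 2 the adjusted p of each of the 4 lay between 0.071 and 0.16. Of 32 neuroblast and proneural genes, 3 rose and 4 fell (3 when adjusted over the list alone; adjusted p = 0.58), insc and pros being 1.44-fold and 1.43-fold lower and brat and neur 1.56-fold and 1.29-fold higher. The median of 0.02 turned to -0.14 with upper quartile scaling, under which 1 rose and 10 fell. Of 24 ecdysone response genes, 2 rose and 5 fell (5 when adjusted over the list alone; adjusted p = 0.38), or 2 and 11 with upper quartile scaling, MsrA rising 2.47-fold and EcR, the hormone receptor, 1.48-fold while Hr4 and ImpE2 fell 1.52-fold and 1.75-fold. Of 35 genes of sensory neurons and dendrites, 3 rose and 9 fell (11 when adjusted over the list alone; adjusted p = 0.18), or 3 and 16 with upper quartile scaling, with pum, fry and brat 1.78-fold, 1.47-fold and 1.56-fold higher and tutl 1.78-fold lower. Of 16 tracheal genes, 5 fell (4 when adjusted over the list alone; adjusted p = 0.10, and 0.0499 without OreR replicate 1), or 13 with upper quartile scaling, Atpalpha, vari, vvl and sty having log2 fold changes of -0.36, -0.49, -0.48 and -0.28. All of these 4 calls ended without mutant replicate 2, with adjusted p-values from 0.057 to 0.11. Of 9 fat body and yolk genes, 2 rose and 3 fell (5 when adjusted over the list alone; adjusted p = 0.74). The genes bmm, a triglyceride lipase, and Yp3 were 1.75-fold and 2.75-fold higher and Acox57D-p and Yp1 2.09-fold and 4.02-fold lower.

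Lists of tissues that embryos should lack gave few tested genes. Of 31 testis genes counted, 6 were tested, r-cup falling 2.36-fold and fzo rising 2.61-fold (2 when adjusted over the list alone; camera adjusted p = 0.77). Of 19 chorion genes 2 were tested and 0 changed by the edgeR test over all genes or over the list alone (adjusted p = 0.74); Cp18 had an unadjusted p of 0.042 and psd of 0.64, and Cp18 passed with upper quartile scaling (adjusted p = 0.043). Of 91 histone genes, 1 was tested, His1:CG33801, which fell 3.57-fold at a mean of 0.54 CPM in OreR (also 1 when adjusted over the list alone; camera adjusted p = 0.37). The log2 fold change of His1:CG33801, -1.84 with all libraries, ran from -2.71 to -1.49 on leaving out each library.

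Usage of bins and junctions, the measure used for the second question of isoform composition, changed in 514 genes. Whether these changes reflect isoform choice or differences between the strains in how reads align was not tested. Of 88820 features tested within their genes, 1618 differed in usage, 500 higher and 1118 lower in the mutant, and these 514 genes were 6.04% of 8510 tested (edgeR diffSpliceDGE, Simes p per gene, Benjamini-Hochberg adjusted p below 0.05). Exonic bins changed in 960 of 53003 cases (1.81%), of which 28.2% were higher (95% Clopper-Pearson interval 25.4 to 31.2). Annotated junctions changed in 630 of 35554 cases (1.77%), of which 34.1% were higher (30.4 to 38). Unannotated junctions changed in 28 of 263 cases (10.6%), 14 in each direction (30.6 to 69.4% higher). Kind and direction were associated among changed features (Fisher's exact test, two-sided p = 0.0043), with the reservation that features of a gene are not independent. By observed counts, without the floor of 3 counts, the share of the gene count differed more than 100-fold in 37 features of 28 genes. Of these, 17 were lower in the mutant and 20 lower in OreR. Changed features with 0 counts in a genotype entered this number whatever their depth. Bin E028 of heph is an example, being at least 63.9-fold lower with the floor. The gene F test of edgeR called 883 genes in place of 514, and limma voom called 2460 features, 951 higher and 1509 lower. With exonic bins alone 875 features were called, with junctions alone 666 in 335 genes, with a mean of at least 50 counts 987, and without mutant replicate 2 there were 967 in 338 genes.

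Junction J024 of Cul4, a cullin scaffold of ubiquitin ligases, held 0.027 ± 0.011% of the gene's count in OreR and 3.94 ± 0.23% in the mutant (SD, n = 3), with the gene level differing by 0.06 on the log2 scale (adjusted p = 0.56 in the edgeR test). Junction J008 of Bacc rose from 11 counts to 5009, and junction J006 of Jasper from 1 count to 1697, a ratio of shares of 967 with a counting interval from 173 to 38200. In the other direction, junction J034 of Efa6, which encodes an exchange factor for Arf6, fell from 2.71 ± 0.33% to 0.045 ± 0.049%, the unannotated junction N045 of smash from 1.19 ± 0.10% to 0.018 ± 0.005%, and junction J033 of PAN3, a subunit of a poly(A) nuclease, from 133 counts to 3 (ratio of shares 68.5, interval 22.9 to 337). Bin E028 of heph, the fly polypyrimidine tract binding protein, had 115 counts in OreR and 0 in the mutant, at least 63.9-fold lower as a share against a floor of 3 counts over the group, while the heph gene rose (log2 fold change 0.79) and 25 of its 70 features changed in usage. Bin E004 of RpS21 went from 2.38 ± 0.25% to 30.6 ± 1.31% of the gene's count with a gene level that differed by 0.11 on the log2 scale (adjusted p = 0.27). Shares of bin E029 of the sodium-proton exchanger gene Nhe2 were 25.5 ± 0.60% and 7.27 ± 0.76%, of bin E001 of cno, the fly afadin, 9.61 ± 1.19% and 2.10 ± 0.51%, and of bin E009 of the translation termination factor gene eRF3 3.65 ± 0.69% and 0.79 ± 0.13% in OreR and the mutant. Bins E017 of CG10353, E020 of wrd, a regulatory subunit of protein phosphatase 2A, and E008 of the gene FBgn0015907 rose to 7.76 ± 0.84%, 6.84 ± 0.60% and 3.40 ± 0.34% from 1.72 ± 0.04%, 1.61 ± 0.23% and 0.81 ± 0.20%. Bin E006 of Tmem214 rose from 0.27 ± 0.01% to 6.38 ± 0.63% in a gene whose level fell (log2 fold change -2.16) and in which 22 of 23 features changed. Adjusted Simes p-values of these 15 genes ran from 7.4e-45 to 3.9e-22.

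**Figure D3:**
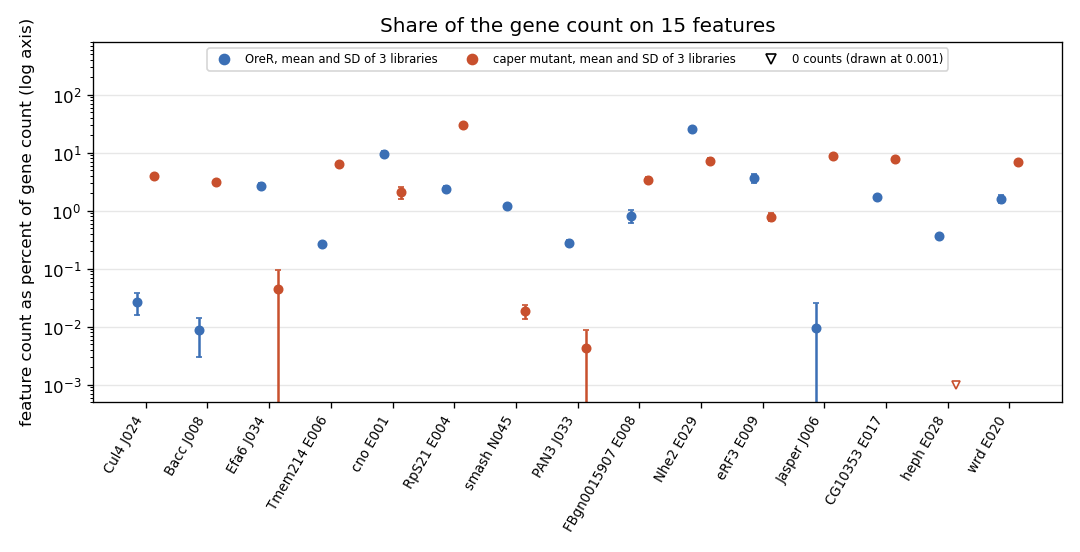
Share of the gene's count held by the feature with the smallest p in each of the 15 genes with the smallest Simes p, in percent on a log axis, as mean and SD of 3 libraries (blue, OreR; red, caper mutant); error bars that reach 0 run off the log axis, and the open triangle marks 0 counts, drawn at 0.001. Bin E004 of RpS21 holds 2.38% in OreR and 30.6% in the mutant, and heph E028 has 0 counts in the mutant.

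Among genes with well-known alternative splicing or a place in sex determination, 5 changed in usage. In Tm1, a tropomyosin gene, 30 of 55 features changed, and junction J047 had 0 counts in OreR and 61 in the mutant, at least 19.2-fold higher as a share against the floor of 3 counts. The share of junction J006 of lncRNA:roX1 rose from 0.21 ± 0.01% to 0.53 ± 0.06%. Bin E025 of unc-13 fell from 6.91 ± 0.52% to 3.73 ± 0.35%, bin E004 of fl(2)d from 6.17 ± 1.08% to 3.67 ± 0.42% and bin E006 of tra2 from 4.81 ± 0.18% to 2.42 ± 0.32% of the gene's count (adjusted Simes p from 4.5e-06 to 0.033). The fl(2)d feature lost its call without OreR replicate 2 (adjusted p = 0.072), and the fl(2)d and tra2 features without mutant replicate 2 (0.15 and 0.16). In level, 4 of 30 classic alternative splicing targets rose and 12 fell (16 when adjusted over the list alone; median -0.25), or 3 and 18 with upper quartile scaling. The list did not pass camera (adjusted p = 0.095) but passed without OreR replicate 1 (0.0497). Its members unc-13, tra2 and arm were 1.57-fold, 1.43-fold and 1.28-fold higher and ps was 1.54-fold lower. For usage, 9 of 63 splicing factors (14.3%) and 3 of 8 heat shock genes changed, against 6.04% of all genes tested, and both lists had an adjusted p of 0.18 (Fisher's exact test over 28 lists, two-sided). The 9 splicing factors were heph, hrg, Acn, sqd, Hrb98DE, fl(2)d, SF1, B52 and tra2.

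Genes changed in usage were also more often changed in level. Of 8510 genes tested for both, 375 of the 514 with changed usage (73.0%) changed in level, against 48.0% of the others and 254 expected (odds ratio 2.92, 95% interval 2.39 to 3.60, two-sided Fisher's exact p = 9.8e-29). Within quartiles of expression the odds ratio was 2.23 (exact Mantel-Haenszel p = 1.4e-15). Of the 375 genes, 293 were higher and 82 lower in the mutant.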

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

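All alternatives were planned except the run without mitochondrially encoded genes (4805 genes changed), which was chosen after seeing the data. Counts of changed genes lay between 4547 and 5013 with DESeq2, DESeq2 size factors, no filter, the replicate block or counts from exonic bins, and 3897 of 8289 genes changed with counts from annotated junctions. Upper quartile scaling called 5835 genes, 3566 of them lower. A 2-fold minimum left 1309 genes, 663 higher and 646 lower. Leaving out each library gave 3169 to 4376 genes, 2194 to 2723 higher and 975 to 1653 lower, the lowest counts coming without mutant replicate 2; without mutant replicate 3 there were 3633 genes, 1282 of them lower, and fewer samples entered each of these fits. Features with changed usage numbered 967 to 1517 (323 to 467 higher, 644 to 1050 lower) and genes 338 to 478 on leaving out a library, again lowest without mutant replicate 2. They numbered 2460 (951 higher) with limma voom, 875 (242 higher, 633 lower) with exonic bins alone, 666 (259 higher, 407 lower, in 335 genes) with junctions alone and 987 (302 higher, 685 lower) with a mean of at least 50 counts, the last 3 testing fewer features; the gene F test called 883 genes. Lists past the threshold numbered 9 to 13 on leaving out a library, 0 of 30 with an estimated correlation (1 at an unadjusted p below 0.05 in camera), 6 with directional fry and 28 with mixed fry. Over the named genes, 64 alternative values of 1854 lost their call, 2 gained it and 1 called value turned, Hsp60A, at 0.13 on the log2 scale with counts from annotated junctions; the cause was not tested. The uncalled value of psd turned from 0.19 to -0.002 without OreR replicate 3. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated across genes at 0.09, -0.01 and 0.60, and not every library correlated best with its own number. With the replicate block 4943 genes, 1716 features and 536 usage genes were called, and the glial and immune lists had an adjusted p of 0.094. The caper gene was not analysed here, so no setting was varied for it, and settings meant for a table without raw counts were not needed. At the depth and replicate number of these libraries, 18% of features raised 1.5-fold were recovered in simulation.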

Other observations

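Tests on symbol families, on the mitochondrial genes, on scaling and on the within-genotype component were chosen after the results were seen. Those on the 200 tested genes nearest caper, on neighbouring copies, on the share of the list difference left and on other splits of the libraries were not. Grouped by the letters of their symbols, 62 families had at least 8 tested genes, and 7 passed camera with a preset correlation, while 0 passed with an estimated correlation (camera adjusted p = 0.878 for each of the families named here). Of 15 Taf genes, which encode subunits of general transcription factor complexes, 12 rose (median log2 fold change 0.75, adjusted p = 0.00025 with the preset correlation). Of 15 Pros genes, which encode subunits of the proteasome core, 12 rose and 1 fell (median 0.80), of 12 Prp genes of pre-mRNA processing 11 rose (0.61), of 21 Nup genes of the nuclear pore 12 rose and 1 fell (0.54), and of 28 Polr genes of the RNA polymerases 14 rose (0.26). Among 14 GstE genes 7 rose and 4 fell, and among 40 Cpr cuticle genes 11 fell and 2 rose (median -1.16). With upper quartile scaling these medians were 0.59, 0.65, 0.46, 0.38, 0.10, 0.36 and -1.31, in the order given.

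Genes beside caper in the reference order, chosen after values were seen, were either higher in the mutant or not past the threshold. MME1, Rab30, Mnn1 and Nuf2 were higher in the mutant, with log2 fold changes of 0.37, 0.93, 0.44 and 1.14, whereas Gart and CG31908 had 0.01 and -0.01 and did not pass the threshold. Changed genes made up between 45.3% and 54.9% of the tested genes on each of the arms 2L, 2R, 3L, 3R, 4 and X.

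With the preset correlation of camera, the neuron, cuticle, muscle, gut and hemocyte lists were lower and the splicing factor and cell cycle lists higher in the mutant, calls lost with an estimated correlation (adjusted p = 0.60 for gut and 0.835 for the others), and the trachea, sensory neuron and fat body lists did not pass. A scaling factor per library would move every gene alike, but the medians of the splicing factor and neuron lists lay 1.11 apart (SE 0.26 over the 3 libraries of each genotype), which argues against scaling as the cause. A candidate explanation is a difference in mean embryo age, in that libraries of the same genotype also varied along these genes: the main within-genotype component (51.6% of that variance) correlated with the genotype difference at r = 0.42 across genes, which are not independent replicates, against 0.09 or less in size for components 2 to 4. After removing it, 0.47 of the difference between the 2 lists was left, so whether age is the whole cause is open. Embryos collected at a younger age and mutant embryos that develop more slowly would look alike here, and an effect of caper on these transcripts was not tested apart from strain.

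Transcripts of mt:CoI, mt:CoII, mt:ND1 and mt:Cyt-b were at 0.37 to 0.55% of the OreR level in the mutant, and mt:ND6 went from 76 counts in OreR to 0 (adjusted p = 0.0011 in the edgeR test). Mismatches scattered along the mitochondrial genome of the strain would reduce the genes unequally, and over the 5 tested genes with counts in both genotypes the log2 fold changes had a standard deviation of 3.3, but 0.25 without mt:ND5, so the spread rests on a single gene and this stays open. A loss of all mitochondrial transcripts is a candidate explanation that stays open too: 5 of the 6 tested fell, and mt:ND5 changed by only -0.39 on the log2 scale, yet it had 0.48% of the counts of mt:CoI in OreR, and whether they came from the mitochondrial genome is not known without reads. No test was run of a second copy of these sequences in the genome reference used by the authors, or of a different way of selecting RNA. A biological difference between the strains was not tested.

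Genes changed at least 8-fold numbered 118. Linkage to the caper locus was tested as a cause, and 1.7% of those placed in the reference order lay among the 200 tested genes nearest caper (2 genes, 2.3 expected), which argues against it. Adjacent tested genes that both changed at least 8-fold in opposite directions were few. Of the 110 nuclear genes, 3.6% had such a neighbour (4 genes, 1.2 on average under 10000 shuffles, permutation p = 0.12), as in CG32640 (-5.05) beside CG32641 (3.65). Reads moved to a copy that was untested, not adjacent or less changed would escape this count. It therefore sets no limit on reads moved between copies. Neighbours changed at least 8-fold the same way were found for 19 genes (1.2 under shuffling, permutation p = 1e-04, the smallest these shuffles can give), in runs such as LManIII, LManIV, LManV and LManVI, or CG14418, CG14419 and CG3588, all lower. Deletions or regional silencing in either strain, unlinked to caper, were not tested and stay open.

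With 3 libraries of each genotype there are 10 splits, too few for a share under 0.05. The genotypes gave 4811 changed genes, 1618 features and 514 genes with changed usage, and the highest of the other splits gave 0 of each in edgeR (387 genes, 271 features and 7 genes at an unadjusted p below 0.05). Lists behaved otherwise: the genotypes gave 11 and the highest of the other splits gave 17 with the preset correlation. Of the 10 splits, the genotypes included, 6 gave at least 11 lists, and the lowest of the others gave 7. The number of lists called with the preset correlation therefore does not set the genotypes apart from the other splits. Each of the other splits sets 2 libraries of a genotype and 1 of the other against the reverse, so part of the genotype difference stays in it. The genotype difference also adds to the spread within each of its groups, which lowers the calls. The 0 calls of the other splits therefore do not measure what libraries without a genotype difference would give.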
